A study of Mus musculus with 15 samples.

How the data were processed

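The deposited count table gave gene counts for 15 libraries, as whole numbers, and all fits below start from it. A second deposited table held normalized values on the log2 scale for the same libraries, and was used only as a check and for an alternative placement of the groups. Per the submitters' processing notes, reads were aligned to mm10 with STAR and the authors used DESeq2. Versions, the counting tool, the annotation and the strand setting are not given in the sources used here. Over 4312 genes with a mean count of at least 1000, differences between libraries in the deposited log2 table and differences from DESeq2 size factors computed here had a median absolute gap of 0.007 and a highest gap of 1.8. The deposited log2 value at 0 counts was 5.566.

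Of 49585 genes in the table, 49326 had a symbol and were matched by identifier in GENCODE M21, which gave coordinates and gene types. The filter filterByExpr of edgeR kept 15223 genes with enough counts for the group sizes. Counts were scaled by TMM factors, and all 15 libraries were fitted in one quasi-likelihood model of edgeR with a term per group (prior degrees of freedom 5.73). The design had 7 comparisons. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested within a comparison. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. CPM values are counts over TMM-scaled library totals, and log2 CPM used a prior count of 2.

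The comparisons, tests, gene lists, rule for naming genes and most alternatives were chosen before the data were examined. In each comparison the named genes were, first, the 5 higher and 5 lower genes with the largest fold change among those that passed, had a mean CPM of at least 10 in the higher group, a symbol that is not a clone or predicted-gene name, and libraries that did not overlap. Second came up to 4 members of each described list with the largest fold change among those that passed. The last part was a fixed set: Aurka, Plk1, Spry4, Dusp6, Etv4, Egr1, Klf4, Esrrb, Nanog, Pou5f1, Fgf5, Otx2, Dnmt3b, Axin2, Socs3, Podxl, Cdkn1a, Mdm2, T and Gata6.

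The 22 gene lists held 308 genes, each in 1 list. They covered naive and core pluripotency, the formative or primed state, targets of ERK, Wnt, LIF and STAT3, and Nodal and Activin signalling, polarity, lumen and junctions, basement membrane and integrins, mitosis, DNA replication, p53 targets, stress response, cholesterol synthesis and glycolysis. The other 7 held markers of other cells or states: primitive endoderm, mesoderm, neuroectoderm, trophoblast, germline, the 2-cell-like state and fibroblasts. Each list was tested against all other genes with camera of limma on voom log2 CPM, two-sided, with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated from the data was run beside it, and so was fry of limma, which asks whether a list's genes move one way on balance without comparing them with other genes. With members at 0 counts set to the bound that the limit of 3 counts allows, medians of the formative list moved most in PD032 against 2iLif, from 3.02 to 2.57, and the fibroblast median in the combination against Aurka inh from -1.51 to -0.82.

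For a gene at 0 counts in a group, the fold is a lower bound against 3 counts over the whole group. With 1 to 3 counts, a ratio of counts per total is given with its 95% interval. Positions between 2iLif and FGF2/Activin are projections of log2 CPM on the difference between the means of both groups, over genes that passed and differed at least 2-fold. Pairs of inhibitor groups were compared by exact two-sided permutation tests.

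Whether equal replicate numbers mark pairs was checked by the correlation, across genes, of deviations from the group mean. Genes are not independent replicates in such a correlation, and the deviations of a group sum to 0, so the values for its 3 libraries depend on each other. Among the inhibitor groups, libraries with the same number had r from 0.17 to 0.483, and 8 of 9 libraries matched best with their own number. Between FGF2/Activin and 2iLif r lay between -0.026 and 0.00713, and across the naming styles between -0.0448 and 0.0654. The comparisons among inhibitor groups were therefore also fitted with replicate number as a block, as an alternative.

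The fits were tested on simulated counts for 15223 genes with 200 changed genes per comparison. Genes changed 4-fold were recovered in 92.4% to 98.5% of cases, 2-fold in 71.6% to 85.1% and 1.5-fold in 56.7% to 68.7%. Of 14569 unchanged genes tested in the comparison of FGF2/Activin with 2iLif, 21 were called, and the other 6 comparisons called 4 to 11. Each gene was simulated with the same spread in all groups. In the data the biological coefficient of variation was 1.78% in FGF2/Activin and 4.53% in 2iLif. It was 9.24% in PD032, 11% in Aurka inh and 8.84% in the combination, so false calls under such unequal spread were not tested. A list shifted 2-fold was found in 7 of 7 comparisons, with 0 of the 20 other lists called by camera in each. Genes were simulated independently, whereas the estimated correlation of the naive list in FGF2/Activin against 2iLif was 0.5. False calls of lists with correlated members were thus not tested. Groups placed at 0.25, 0.5 and 0.75 between 2iLif and FGF2/Activin were recovered at 0.249, 0.496 and 0.745. They were simulated exactly on the line between both media, so this checks the calculation and not groups that lie off the line.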

Results

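RNA sequencing of poly(A)-selected RNA covered 15 libraries of mouse E14 embryonic stem cells, 3 from each of 5 culture conditions. Per the labels, the cells were maintained with 0.4 µM PD0325901, which blocks MEK, 3 µM CHIR99021, which blocks GSK3, and 4 ng/ml Lif, then embedded in growth factor reduced Matrigel at 2000 cells per µl. The gel was covered with N2B27 medium carrying 2iLif, FGF2/Activin, PD032, an inhibitor of Aurora kinase A written as Aurka inh, or PD032+ Aurka inh, called the combination here. The labels also write FGF2/Activin as FAK, expand neither FAK nor PD032, name no Aurora compound, and give no inhibitor dose or treatment time. No group grew in N2B27 alone, so each inhibitor could be compared only with the other media.

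Total counts per library ran from 15199507 to 15818758 in 2iLif, from 15234243 to 15703321 in FGF2/Activin, from 18421904 to 22683616 in PD032, from 16010904 to 21691325 in Aurka inh and from 19304585 to 24202544 in the combination. Of 49585 genes in the count table, 15223 had counts high enough to be tested. Gene values are counts scaled to library size (CPM), mean ± SD over n = 3 libraries per group, and fold changes and adjusted p-values are from edgeR. The p-values measure only the spread between these libraries, whose replicates may be technical. That spread was estimated over all 5 groups together. The smaller spread within FGF2/Activin and 2iLif can therefore make p-values among the inhibitor groups too small. Every pair of replicates differed by more than sampling noise, with a chi-squared per degree of freedom from 1.24 within FGF2/Activin to 19.2 within the inhibitor groups. Intervals and limits for low counts cover counting error only.

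Positions are on mm10 with GENCODE M21 coordinates. Klf4 (ENSMUSG00000003032) spans 55527143 to 55532466 on chromosome 4, Fgf5 (ENSMUSG00000029337) 98254184 to 98277030 on chromosome 5, and Spry4 (ENSMUSG00000024427) 38586247 to 38601415 on chromosome 18. Etv4 (ENSMUSG00000017724) and Axin2 (ENSMUSG00000000142) lie on chromosome 11, from 101769742 to 101785371 and from 108920349 to 108950783. Sp5 (ENSMUSG00000075304) spans 70474923 to 70477729 and Aurka (ENSMUSG00000027496) 172356190 to 172370535, both on chromosome 2. All are protein-coding genes, and the values are counts over whole genes. Nanog, Pou5f1, Dppa3 and Dppa5a have processed pseudogenes, so their counts depend on how shared reads were assigned. The strand setting of the counting was not given, so antisense or overlapping transcripts can add to a gene's count.

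The first 3 principal components of log2 CPM held 52.2%, 21.2% and 13.1% of the variance. The first ran from 2iLif, at -84.5 to -83.8, to FGF2/Activin, at 85 to 86.6. On the second the 9 inhibitor libraries lay between 20.7 and 35.4 and the other 6 between -47.5 and -43.8. The labels name the files of 2iLif and FGF2/Activin in one style and those of the inhibitor groups in another. This split of the libraries was the only one of 10 splits of the groups into 2 and 3 to be marked by pseudogenes: 37 of its 76 separating genes, 48.7%, were pseudogenes, against 4.97% of the genes tested and at most 1.38% in the other splits (Fisher's exact test, adjusted p = 2.6e-27). Comparisons across the naming styles therefore carry a possible batch difference that no group in the design crosses. The comparison of FGF2/Activin with 2iLif and the 3 comparisons among inhibitor groups stay within a style.

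**Figure D1:**
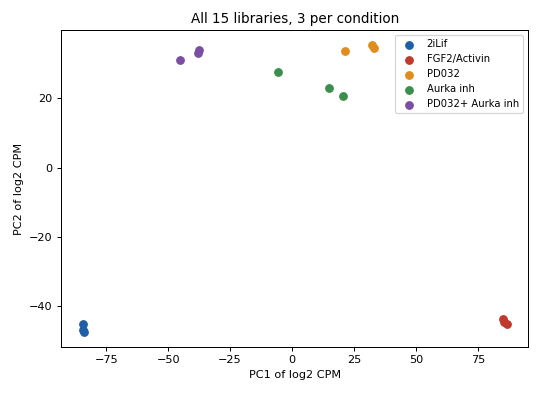
Each point is a library, placed by its scores on the first (52.2% of variance) and second (21.2%) principal components of log2 CPM. The 9 inhibitor libraries sit above the 6 libraries of 2iLif and FGF2/Activin on the second component.

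FGF2/Activin against 2iLif compares cells moved to growth factor medium with cells kept under the maintenance inhibitors. Naive pluripotency genes were lower in FGF2/Activin. Klf4, a transcription factor of that network, fell from 338 ± 8.81 to 3.8 ± 0.168 CPM, a log2 fold change of -6.47 (SE 0.11, edgeR adjusted p = 3.1e-16). Nanog fell from 530 ± 20.8 to 40.4 ± 3.4 CPM and Esrrb from 863 ± 26.2 to 30.3 ± 2.66 CPM. Genes of the formative state were higher: Fgf5, which encodes a growth factor of the early epiblast, had 3849 counts against 3, a count ratio of 1290 (95% interval 440 to 6250). Otx2, a transcription factor of the same stage, rose by a log2 fold change of 4.17 to 170 ± 2.92 CPM. Pou5f1, expressed in both states, had 701 ± 18.1 CPM against 829 ± 24.9 (edgeR adjusted p = 0.023, and 0.076 without FGF2/Activin replicate 2, the highest of a range from 3.5e-07 over the settings run).

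Of 16 naive genes 14 fell and 2 did not pass (15 fell adjusted over the list alone; limma camera adjusted p = 7.4e-09, and 0.16 with an estimated correlation). Of 16 formative genes 15 rose and 1 did not pass, both over all genes and adjusted over the list alone (camera adjusted p = 7.4e-09, and 0.15 with an estimated correlation). All 9 measured LIF and STAT3 targets fell, among them Socs3, a feedback inhibitor of that pathway, from 133 ± 1.03 to 2.25 ± 0.0972 CPM (camera adjusted p = 1.8e-06, and 0.032 with an estimated correlation). Of 20 ERK targets 13 rose, 2 fell and 5 did not pass, with the same 13 and 2 adjusted over the list alone (camera adjusted p = 0.0041, and 0.16 with an estimated correlation). Among them Dusp6, a phosphatase that acts on ERK, rose from 33 ± 0.691 to 138 ± 4.14 CPM, and Etv4, an ETS transcription factor, from 28.6 ± 2.22 to 92.6 ± 5.59 CPM. Spry4, a feedback inhibitor of receptor tyrosine kinases, rose less, by a log2 fold change of 0.38.

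Of 9 Nodal and Activin targets 7 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.016, and 0.13 with an estimated correlation). Lefty1, an inhibitor of Nodal, rose from 0.547 ± 0.317 to 226 ± 10.5 CPM. Of 18 genes for polarity, lumen and junctions 14 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 4.4e-05, and 0.18 with an estimated correlation). Podxl, which coats the apical surface and lumen, rose from 19.7 ± 1.49 to 202 ± 2.11 CPM. Cholesterol synthesis genes rose in 14 of 17 cases and did not pass in 3 (camera adjusted p = 0.00047, and 0.39 with an estimated correlation). Germline genes rose in 8 of 10 cases and did not pass in 2 (camera adjusted p = 0.0046, and 0.083 with an estimated correlation). In the other settings run, the highest camera adjusted p of these 8 lists was 0.022.

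Wnt targets moved both ways, with 3 of 12 higher and 7 lower (camera adjusted p = 0.2). Axin2, a feedback inhibitor of Wnt signalling, fell from 124 ± 6.01 to 12.8 ± 1.34 CPM, Sp5 had 1 count against 2974, a count ratio of 2960 (95% interval 532 to 117000), and Lef1 rose from 1.78 ± 0.201 to 75.2 ± 2.15 CPM. Core pluripotency genes split into 5 higher and 5 lower of 10 (camera adjusted p = 0.66), and basement membrane and integrin genes into 7 and 7 of 14 (camera adjusted p = 0.57). Mitosis genes had 7 higher and 10 lower of 28 (camera adjusted p = 0.7). Among these Aurka, the kinase the Aurora inhibitor is named for, had 144 ± 2.72 against 169 ± 5.65 CPM. DNA replication genes had 12 higher and 2 lower of 16 (camera adjusted p = 0.059), p53 targets 8 and 3 of 16 (0.15) and stress response genes 6 and 5 of 12 (0.84). Glycolysis genes had 7 higher and 4 lower of 14 (camera adjusted p = 0.7), with a median log2 fold change of 0.109 and a mean of -0.13.

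Apart from the germline genes, no list of other cell types passed in camera. Primitive endoderm genes had 3 higher and 2 lower of 7 measured (camera adjusted p = 0.66), mesoderm genes 3 and 5 of 10 (0.6), neuroectoderm genes 2 and 2 of 5 (0.6), trophoblast genes 2 and 2 of 5 (0.96) and fibroblast genes 4 and 1 of 5 (0.35). Gata6, a primitive endoderm gene, was too low to test, at 0.429 CPM in its highest library, and none of the 7 genes of the 2-cell-like state was tested. Among the genes named for the size of their change was Car4, a carbonic anhydrase, with 2178 counts against 0, at least 729-fold higher with the limit of 3 counts taken over the group. Ntn1, which encodes netrin 1, fell from 421 ± 2.55 to 1.53 ± 0.246 CPM. In all, 5063 genes were higher and 4962 lower.

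The combination against PD032 shows what the Aurora inhibitor changed in the presence of PD032. Naive genes were higher with both inhibitors. Nanog rose from 121 ± 8.67 to 385 ± 17.5 CPM, a log2 fold change of 1.67 (SE 0.10, edgeR adjusted p = 2.9e-09), Klf4 from 14.3 ± 2.16 to 48.3 ± 1.15 CPM and Tbx3 from 5.64 ± 2 to 95.4 ± 14.2 CPM. Formative genes were lower: Fgf5 fell from 18.7 ± 2.04 to 0.288 ± 0.0688 CPM and Otx2 from 222 ± 6.03 to 53.7 ± 1.15 CPM. Axin2 rose from 4.11 ± 0.626 to 80.1 ± 2.24 CPM, a log2 fold change of 4.29 (SE 0.095, edgeR adjusted p = 1.3e-14). Sp5, another Wnt target, had 277 counts against 0, at least 88-fold higher.

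Of 16 naive genes 13 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 3.4e-09, and 0.17 with an estimated correlation). Of 16 formative genes 13 fell and 3 did not pass (14 fell adjusted over the list alone; camera adjusted p = 2.8e-08, and 0.17 with an estimated correlation). Wnt targets rose in 8 of 12 cases and fell in 2 (camera adjusted p = 0.014, and 0.17 with an estimated correlation). With replicate number as a block among the 9 inhibitor libraries, the Wnt list had an adjusted p of 0.058, the highest of its range from 0.0056. ERK targets rose in 10 of 20 cases and fell in 3 (camera adjusted p = 0.014, and 0.21 with an estimated correlation). Among them Etv4 went from 1.44 ± 0.246 to 3.98 ± 0.037 CPM and Spry4 from 0.149 ± 0.113 to 0.647 ± 0.162 CPM, against 28.6 ± 2.22 and 43.6 ± 0.597 CPM in 2iLif, across the naming styles. Dusp6 did not pass, at 11.7 ± 0.202 against 12 ± 1.77 CPM, and its fold change turned positive without PD032 replicate 2 (log2 0.08).

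Cholesterol synthesis genes fell in 16 of 17 cases and did not pass in 1 (camera adjusted p = 1.2e-07, and 0.21 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, fell from 871 ± 16.3 to 505 ± 15.5 CPM. Polarity, lumen and junction genes fell in 11 of 18 cases and did not pass in 7 (11 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00075, and 0.22 with an estimated correlation). Podxl fell from 373 ± 40.1 to 29.4 ± 9.44 CPM. Neuroectoderm genes fell in 4 of 5 measured cases, among them the Notch ligand Dll1 from 48.3 ± 3.3 to 3.05 ± 0.665 CPM (camera adjusted p = 0.0062, and 0.17 with an estimated correlation). Glycolysis genes rose in 6 of 14 cases and fell in 1 (camera adjusted p = 0.037, and 0.37 with an estimated correlation). The glycolysis list missed the threshold in 4 of its other settings, whose adjusted p ran from 0.0092: 0.055 with library size alone, 0.074 and 0.083 without replicates 1 and 3 of the combination, and 0.098 without PD032 replicate 2. For the 6 lists other than Wnt and glycolysis the highest was 0.027.

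Of 28 mitosis genes 5 rose, 3 fell and 20 did not pass (camera adjusted p = 0.75), with a median log2 fold change of -0.0124 and a mean of 0.0132. Aurka had 181 ± 2.41 against 163 ± 10.2 CPM (edgeR adjusted p = 0.027), and its adjusted p ran from 0.0037 to 0.15. It was 0.067 without replicate 2 of the combination, and 0.082 and 0.15 without PD032 replicates 1 and 3. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 62.1 ± 1.12 to 142 ± 10.3 CPM, while 8 of 16 p53 targets fell and 1 rose (camera adjusted p = 0.089). Among the genes named for the size of their change, the homeobox gene Nkx1-2 rose from 0.16 ± 0.0475 to 43.1 ± 7.83 CPM. Foxd4, a forkhead factor, fell from 34.8 ± 6.71 to 0.192 ± 0.105 CPM. In all, 3042 genes were higher and 3618 lower, and 2443 and 4027 with scaling by library size alone.

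**Figure D2:**
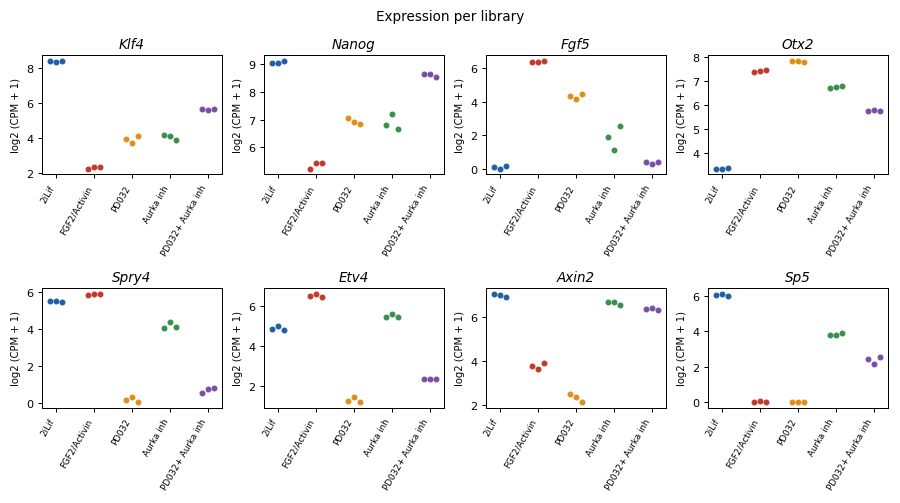
Points are single libraries, 3 per condition, with log2 of CPM plus 1 on the vertical axis of each gene's panel. Spry4 had 0.149 CPM in PD032 and 17.1 in Aurka inh, Axin2 4.11 in PD032 and 80.1 in the combination, and Nanog 121, 119 and 385 CPM in PD032, Aurka inh and the combination.

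The combination against Aurka inh shows what PD032 changed in the presence of the Aurora inhibitor. ERK targets were lower: Spry4 fell from 17.1 ± 2.04 to 0.647 ± 0.162 CPM, a log2 fold change of -4.70 (SE 0.16, edgeR adjusted p = 1.6e-11), and Dusp6 from 43.5 ± 4.4 to 11.7 ± 0.202 CPM. Etv4 fell from 45.3 ± 2.98 to 3.98 ± 0.037 CPM. Naive genes were higher, with Nanog rising from 119 ± 24.1 to 385 ± 17.5 CPM and Prdm14, a naive transcription factor, from 1.89 ± 1.15 to 19.8 ± 0.51 CPM. The formative gene Pou3f1 fell from 34.2 ± 7.36 to 3.14 ± 0.736 CPM. T, a transcription factor of the primitive streak, fell from 8.21 ± 1.23 to 0.971 ± 0.216 CPM.

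Of 20 ERK targets 12 fell and 8 did not pass (13 fell adjusted over the list alone; camera adjusted p = 1.3e-07, and 0.048 with an estimated correlation). Egr1, an immediate early gene of that list, did not pass, at 29.2 ± 24.8 against 54.9 ± 28.2 CPM (edgeR adjusted p = 0.38). With a replicate block among the 9 inhibitor libraries it was 0.0064, in a range from 1.8e-21, with no filter on low counts, to 0.67. Given the spread of Egr1 between libraries, the lowest value cannot be taken at face value. Naive genes rose in 14 of 16 cases and did not pass in 2 (15 rose adjusted over the list alone; camera adjusted p = 3e-13, and 0.12 with an estimated correlation). Formative genes fell in 11 of 16 cases and rose in 1 (camera adjusted p = 2.3e-07, and 0.19 with an estimated correlation). Mesoderm genes fell in 7 of 10 cases and did not pass in 3 (camera adjusted p = 0.0011, and 0.19 with an estimated correlation). Wnt targets fell in 5 of 12 cases and rose in 1 (camera adjusted p = 0.016, and 0.12 with an estimated correlation): Axin2 fell from 97.2 ± 4.69 to 80.1 ± 2.24 CPM, and Notum, a secreted Wnt inhibitor, rose from 13.3 ± 3.36 to 52.7 ± 2.5 CPM.

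Basement membrane and integrin genes rose in 9 of 14 cases and fell in 3, among them the nidogen gene Nid1, from 30 ± 10.5 to 161 ± 29.8 CPM (camera adjusted p = 0.03, and 0.37 with an estimated correlation). Over the other settings this list's adjusted p ran from 0.009 to 0.077, the highest without Aurka inh replicate 2. Polarity, lumen and junction genes fell in 6 of 18 cases and rose in 2 (4 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.031, and 0.45 with an estimated correlation). Their adjusted p ran from 0.0029 to 0.087, the highest without Aurka inh replicate 1, and was 0.058 without replicate 2 of the combination. DNA replication genes fell in 6 of 16 cases and rose in 1 (camera adjusted p = 0.016, and 0.2 with an estimated correlation). For the other 6 lists the highest adjusted p in the other settings was 0.039.

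Of 28 mitosis genes 2 rose, 3 fell and 23 did not pass (camera adjusted p = 0.36). LIF and STAT3 targets had 3 higher and 2 lower of 9 (camera adjusted p = 0.36), with a median log2 fold change of 0.153 and a mean of -0.271. Among the rising genes named for the size of their change, Cyp1a1, an oxidase induced by foreign compounds, went from 2.52 ± 2.04 to 56.1 ± 33.6 CPM. Pmaip1, which promotes apoptosis, fell from 74.6 ± 12.8 to 11.3 ± 0.627 CPM. In all, 2837 genes were higher and 2474 lower. Which count was larger depended on the scaling, with 2635 higher and 2643 lower by RLE and 2611 and 2701 by library size alone.

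PD032 against Aurka inh compares the single inhibitors. ERK targets were lower in PD032: Spry4 had 0.149 ± 0.113 against 17.1 ± 2.04 CPM, a log2 fold change of -6.85 (SE 0.21, edgeR adjusted p = 1.1e-12), and Etv4 had 1.44 ± 0.246 against 45.3 ± 2.98 CPM. Wnt targets were lower as well: Axin2 had 4.11 ± 0.626 against 97.2 ± 4.69 CPM, a log2 fold change of -4.57 (SE 0.095, edgeR adjusted p = 8.4e-15), and Sp5 had 0 counts against 757, at least 277-fold lower. Klf4, at 14.3 ± 2.16 and 15.7 ± 1.84 CPM, and Nanog, at 121 ± 8.67 and 119 ± 24.1 CPM, did not pass the threshold. Nanog had an adjusted p of 0.84 in edgeR and of 0.044 without Aurka inh replicate 2, in a range from 0.016 to 0.99. Esrrb had 178 ± 13.7 against 151 ± 32.1 CPM (edgeR adjusted p = 0.091, 0.046 with a replicate block and 0.0024 without Aurka inh replicate 2, in a range from 0.00034 to 0.44). Fgf5 was higher in PD032, at 18.7 ± 2.04 against 2.92 ± 1.83 CPM.

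Of 20 ERK targets 13 were lower and 1 higher in PD032 (14 and 1 adjusted over the list alone; camera adjusted p = 8.9e-09, and 0.027 with an estimated correlation). Egr1 had 13.8 ± 12.8 against 54.9 ± 28.2 CPM (edgeR adjusted p = 0.052, and 0.0043 with a replicate block). Its adjusted p ranged from 7.7e-90, in the fit with no filter on low counts, to 0.16. With libraries that spread so widely, the lowest value cannot be taken at face value. The adjusted p was 0.022 without Aurka inh replicate 2 and 0.031 without PD032 replicate 3. Of 12 Wnt targets 8 were lower and 1 higher (9 and 2 adjusted over the list alone; camera adjusted p = 0.00064, and 0.027 with an estimated correlation). Of 16 naive genes 4 were higher and 3 lower (camera adjusted p = 0.84), with 4 and 4 adjusted over the list alone. Fry's test for change in either direction had an adjusted p of 3.1e-11 for this list. That test passed for every other list tested here except germline (fry adjusted p = 0.43), so it does not single out the naive genes. Formative genes were higher in 8 of 16 cases and lower in 3 (camera adjusted p = 0.046, and 0.51 with an estimated correlation), and their adjusted p ran from 0.011 to 0.15 over the other settings. Leaving out Aurka inh replicate 2, PD032 replicate 1 or PD032 replicate 3 gave 0.15, 0.067 and 0.062. Polarity, lumen and junction genes were higher in 8 of 18 cases and lower in 1 (camera adjusted p = 0.042, and 0.51 with an estimated correlation). The same 3 libraries left out gave 0.17, 0.066 and 0.062 for this list, in a range from 0.014.

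Genes of 2 germ layers moved apart. Mesoderm genes were lower in PD032 in 6 of 10 cases and did not pass in 4, among them T at 0.123 ± 0.0424 against 8.21 ± 1.23 CPM (camera adjusted p = 0.0059, and 0.25 with an estimated correlation). Neuroectoderm genes were higher in 4 of 5 measured cases, among them the eye and brain factor Pax6 at 11.5 ± 3.71 against 0.735 ± 0.291 CPM (camera adjusted p = 0.0013, and 0.065 with an estimated correlation). Basement membrane and integrin genes were higher in 11 of 14 cases and lower in 1 (camera adjusted p = 0.00038, and 0.14 with an estimated correlation). Cholesterol synthesis genes were higher in 14 of 17 cases and did not pass in 3 (camera adjusted p = 5.4e-05, and 0.32 with an estimated correlation). DNA replication genes were lower in 11 of 16 cases and did not pass in 5 (camera adjusted p = 6e-04, and 0.093 with an estimated correlation). Apart from the formative and polarity lists, the highest adjusted p in the other settings was 0.015.

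Of 28 mitosis genes 4 were higher and 8 lower in PD032 (camera adjusted p = 0.23), with Aurka at 163 ± 10.2 against 199 ± 8.51 CPM. Signs differed between median and mean for Nodal and Activin targets (log2 0.0627 and -0.614) and for p53 targets (0.186 and -0.0618), neither past the threshold. Lmx1b, a LIM homeobox factor, had 54.6 ± 6.77 against 0.515 ± 0.226 CPM, and Nkx1-2 had 0.16 ± 0.0475 against 36.7 ± 3.53 CPM. In all, 3929 genes were higher and 2999 lower in PD032.

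Positions of the inhibitor groups between 2iLif, set to 0, and FGF2/Activin, set to 1, were taken over 4207 genes that differed at least 2-fold between those media. PD032 lay at 0.643 ± 0.0345, Aurka inh at 0.577 ± 0.0739 and the combination at 0.296 ± 0.0239 (SD, n = 3). The combination differed from PD032 by -0.347 and from Aurka inh by -0.281, each with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow (0.15 after Benjamini-Hochberg adjustment over 3 tests). PD032 and Aurka inh differed by 0.0665 (exact permutation p = 0.2, adjusted 0.2). Paired by replicate number, the 3 differences were 0.0592, 0.11 and 0.0304, all with PD032 higher (exact paired permutation p = 0.25, the smallest that 3 pairs allow). The second library lay nearest 2iLif in each inhibitor group, at 0.603 in PD032, 0.493 in Aurka inh and 0.268 in the combination. Left-out 2iLif libraries fell at 0.011 to 0.017. These positions cross the naming styles, while the differences among inhibitor groups do not. A position gives only the part of a profile along this line. On the second principal component the inhibitor libraries lay at 20.7 to 35.4, apart from both media at -47.5 to -43.8, so a position does not by itself show an intermediate state.

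**Figure D3:**
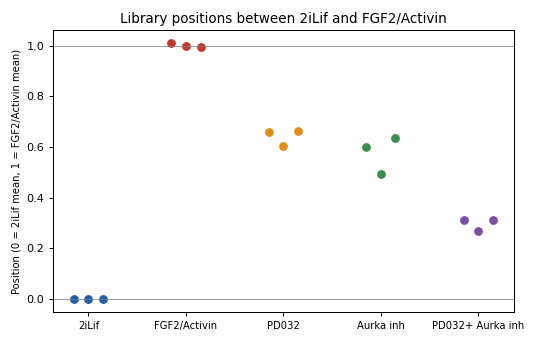
Each point is a library, placed between the mean of 2iLif (0) and the mean of FGF2/Activin (1) on the vertical axis, by condition on the horizontal axis. The combination lay at 0.296, under PD032 at 0.643 and Aurka inh at 0.577.

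PD032 against 2iLif compares PD032 alone with the maintenance medium and crosses the naming styles, as do the next 2 comparisons. Among 756 pseudogenes tested, 259 were lower and 92 higher in PD032. Pseudogene calls were uneven within a style too, with 71 lower and 20 higher in PD032 against Aurka inh, so these counts alone do not single out the style. Klf4 fell from 338 ± 8.81 to 14.3 ± 2.16 CPM, and Fgf5 had 1203 counts against 3, a count ratio of 301 (95% interval 103 to 1460). Otx2 rose from 9.4 ± 0.212 to 222 ± 6.03 CPM. Spry4 fell from 43.6 ± 0.597 to 0.149 ± 0.113 CPM, though Spry4 is also among the genes that separate the naming styles. Axin2 fell from 124 ± 6.01 to 4.11 ± 0.626 CPM, and Sp5 had 0 counts against 2974, at least 1320-fold lower.

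All 9 LIF and STAT3 targets fell (camera adjusted p = 8.8e-08, and 0.016 with an estimated correlation). Naive genes fell in 14 of 16 cases and rose in 1 (camera adjusted p = 8.7e-08, and 0.15 with an estimated correlation), and formative genes rose in 15 of 16 (camera adjusted p = 3.2e-08, and 0.11 with an estimated correlation). ERK targets fell in 10 of 20 cases and rose in 4 (camera adjusted p = 0.012, and 0.15 with an estimated correlation), and Wnt targets fell in 9 of 12 and rose in 2 (camera adjusted p = 0.011, and 0.087 with an estimated correlation). Cholesterol synthesis genes rose in 14 of 17 cases (camera adjusted p = 2.9e-05, and 0.24 with an estimated correlation), with 15 rising adjusted over the list alone. Rises were also called for p53 targets, 12 of 16 with 1 falling (camera adjusted p = 0.0013, and 0.11 with an estimated correlation), and stress response genes, 8 of 12 with 2 falling (camera adjusted p = 0.027, and 0.11 with an estimated correlation). Neuroectoderm genes rose in 4 of 5 cases (camera adjusted p = 0.029, and 0.15 with an estimated correlation) and germline genes in 7 of 10 (camera adjusted p = 0.011, and 0.087 with an estimated correlation).

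Mitosis genes rose in 17 of 28 cases and fell in 2, by a median log2 fold change of 0.158 (camera adjusted p = 0.029, and 0.25 with an estimated correlation). Their adjusted p ran from 0.0052 to 0.066, with 0.066 without PD032 replicate 2 and 0.052 without 2iLif replicate 1. Aurka itself did not pass, at 163 ± 10.2 against 169 ± 5.65 CPM, and its fold change turned positive when scaled by library size alone. DNA replication genes fell in 10 of 16 cases (camera adjusted p = 0.014, and 0.15 with an estimated correlation), in a range from 0.007 to 0.062, the latter with library size alone. For the 10 other lists called here the highest was 0.038. Lmx1b had 3517 counts against 0, at least 880-fold higher. In all, 4881 genes were higher and 4709 lower, against 4794 and 4797 by RLE scaling and 5498 and 3972 with scaling by library size alone.

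Aurka inh against 2iLif compares the Aurora inhibitor alone with the maintenance medium. Of 756 pseudogenes 209 were lower and 110 higher, again across the naming styles. Klf4 fell from 338 ± 8.81 to 15.7 ± 1.84 CPM and Otx2 rose from 9.4 ± 0.212 to 106 ± 3.45 CPM. Dusp4, another ERK phosphatase gene, rose from 2.11 ± 0.267 to 69.8 ± 13 CPM, while Spry4, which also separates the naming styles, fell from 43.6 ± 0.597 to 17.1 ± 2.04 CPM. Axin2 fell by a log2 fold change of only -0.35, to 97.2 ± 4.69 CPM, and Sp5 fell from 65.4 ± 3.17 to 13.3 ± 0.73 CPM. Egr1 was higher (edgeR adjusted p = 0.036), but its adjusted p ran from 2.7e-98 to 0.11, the highest with DESeq2. Given its spread between libraries, the lowest value cannot be taken at face value. Egr1 missed the threshold without each of the 2iLif libraries in turn (0.065, 0.094 and 0.098). It also missed it without Aurka inh replicates 1 (0.1) and 3 (0.075).

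All 9 LIF and STAT3 targets fell (camera adjusted p = 3.4e-08, and 0.013 with an estimated correlation). Naive genes fell in 14 of 16 cases and rose in 1 (camera adjusted p = 1.2e-08, and 0.16 with an estimated correlation), and formative genes rose in 14 of 16 (camera adjusted p = 3.4e-08, and 0.16 with an estimated correlation). Of 20 ERK targets 11 rose and 5 fell (camera adjusted p = 0.13), and of 12 Wnt targets 4 rose and 6 fell (camera adjusted p = 0.42). Mitosis genes rose in 18 of 28 cases and fell in 1 (camera adjusted p = 0.0023, and 0.16 with an estimated correlation). Their median log2 fold change was 0.178, close to 0.158 in PD032 against 2iLif, without the Aurora inhibitor. In the combination against PD032, within a naming style, it was -0.0124. The rise is thus not particular to the Aurora inhibitor. Aurka rose from 169 ± 5.65 to 199 ± 8.51 CPM, and Plk1, a mitotic kinase acting with it, from 153 ± 2.22 to 208 ± 4 CPM. Basement membrane and integrin genes fell in 10 of 14 cases and rose in 4 (camera adjusted p = 0.0045, and 0.24 with an estimated correlation). Rises were called for p53 targets, 11 of 16 with 2 falling (camera adjusted p = 0.0016, and 0.15 with an estimated correlation), and germline genes, 8 of 10 (camera adjusted p = 0.0035, and 0.067 with an estimated correlation). The highest adjusted p of these lists in the other settings was 0.015. Enpp2, which encodes autotaxin, rose from 0.131 ± 0.0639 to 76.9 ± 16.2 CPM. In all, 4398 genes were higher and 4490 lower, but 4564 and 4308 by RLE scaling and 4917 and 3994 by library size alone.

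The combination against 2iLif compares both inhibitors with the maintenance medium, with 202 of 756 pseudogenes lower and 98 higher across the naming styles. Nanog fell from 530 ± 20.8 to 385 ± 17.5 CPM, a log2 fold change of -0.46 (SE 0.10, edgeR adjusted p = 0.0013), and Klf4 from 338 ± 8.81 to 48.3 ± 1.15 CPM. Dnmt3b, a DNA methyltransferase of the formative state, rose from 241 ± 4.69 to 791 ± 72.6 CPM. Fgf5 did not pass, with 19 counts against 3, a count ratio of 4.53 (95% interval 1.33 to 23.9). Its edgeR adjusted p was 0.17, and ran from 0.021 to 0.35 over the other settings. Axin2 fell to 80.1 ± 2.24 CPM, a log2 fold change of -0.63. Socs3 fell from 133 ± 1.03 to 0.239 ± 0.11 CPM.

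All 9 LIF and STAT3 targets fell (camera adjusted p = 4e-08, and 0.01 with an estimated correlation). Naive genes fell in 11 of 16 cases and rose in 1 (camera adjusted p = 0.00027, and 0.38 with an estimated correlation), and formative genes rose in 11 of 16 (camera adjusted p = 7.4e-06, and 0.2 with an estimated correlation). ERK targets had 5 higher and 7 lower of 20 (camera adjusted p = 0.15) and Wnt targets 2 and 6 of 12 (camera adjusted p = 0.098). Mitosis genes rose in 17 of 28 cases and fell in 3 (camera adjusted p = 0.0026, and 0.2 with an estimated correlation), while Aurka did not pass at 181 ± 2.41 CPM except with library size alone (edgeR adjusted p = 0.13, in a range from 0.044 to 0.38). Basement membrane and integrin genes fell in 7 of 14 cases and rose in 1 (camera adjusted p = 0.0056, and 0.21 with an estimated correlation). Rises were called for p53 targets, 9 of 16 with 1 falling (camera adjusted p = 0.002, and 0.16 with an estimated correlation), for glycolysis genes, 9 of 14 with 2 falling (camera adjusted p = 0.013, and 0.39 with an estimated correlation), and for germline genes, 7 of 10 (camera adjusted p = 0.015, and 0.16 with an estimated correlation). The highest adjusted p of these lists in the other settings was 0.033. In all, 3616 genes were higher and 3627 lower, but 3905 and 3310 with scaling by library size alone.

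**Figure D4:**
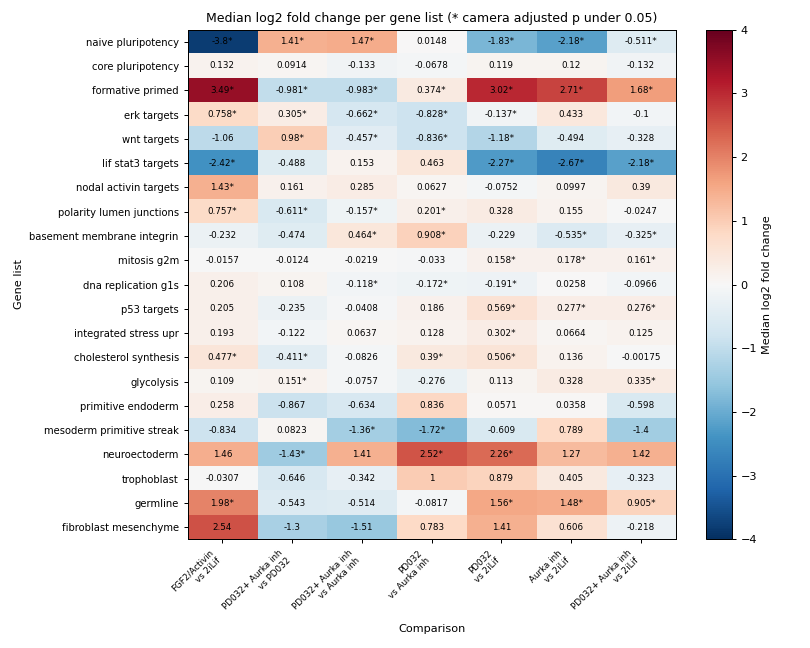
Each cell gives the median log2 fold change of a gene list (vertical axis) in a comparison (horizontal axis), with a star where camera with a preset correlation gave an adjusted p under 0.05. The naive list had a median of -3.8 in FGF2/Activin against 2iLif, 1.41 in the combination against PD032 and 1.47 in the combination against Aurka inh.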

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

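Leaving out the second libraries of the 3 inhibitor groups, blocking by replicate number among the 9 inhibitor libraries alone, placing groups on the deposited log2 values and pairing positions by replicate number were chosen after the data were seen. Named genes gave 694 results. Of these, 690 kept direction and side of the threshold with RLE scaling, 681 with DESeq2 and 680 with scaling by library size alone. With no filter on low counts 670 did so. That fit is a weak check, as its adjusted p-values for Egr1 were far smaller than the spread between libraries allows. All 694 were kept without genes of the mitochondrial genome and the 20 genes with the highest total counts. A replicate block in all 15 libraries kept 690, and the block among 9 inhibitor libraries kept 275 of 284, with 9 passing that had not. Leaving out 1 library kept 4015 of 4153 values, with 120 weaker, 13 stronger and 5 reversed. The reversed values were all of genes that did not pass. Dusp6 in the combination against PD032 had log2 0.089 without the second libraries and between -0.124 and 0.082 with a library left out, the highest without PD032 replicate 2. Mdm2 in the combination against Aurka inh had -0.002 with a stricter filter and -0.001 in a fit of only those groups. Nanog in PD032 against Aurka inh had -0.005 in a fit of only those groups and between -0.085 and 0.199 with a library left out, with -0.085 and -0.012 without Aurka inh replicates 3 and 1 and -0.027 without PD032 replicate 1. Aurka in PD032 against 2iLif had 0.023 with library size alone, and Egr1 there had -0.027 with the replicate block and between -0.667 and 0.701 with a library left out, the lowest without PD032 replicate 3. The cause was not tested. A minimum fold of 2 lowers counts by construction: genes higher and lower became 2525 and 1682 in FGF2/Activin against 2iLif, 567 and 1562 in the combination against PD032, 533 and 848 in the combination against Aurka inh, 1226 and 561 in PD032 against Aurka inh, 2409 and 1195 in PD032 against 2iLif, 1936 and 1375 in Aurka inh against 2iLif, and 1279 and 988 in the combination against 2iLif. At an adjusted p under 0.01, 2012 genes were higher in the combination against PD032 and 1576 lower in the combination against Aurka inh. With only the groups compared in the fit, 1788 were higher in the combination against Aurka inh. Such a fit has fewer libraries to estimate the spread. It also leaves out FGF2/Activin and 2iLif, whose biological coefficients of variation were lower (1.78% and 4.53%) than in Aurka inh (11%) and the combination (8.84%). Which of these lowered the count was not tested. No count of genes moved by over 1.5 times with a library left out, and no position of a group by over 1 SD in the settings run. Leaving out 1 of 3 libraries cannot move their mean by 1 SD of the same libraries. For positions, only the settings that keep all libraries test this. With an estimated correlation, camera called 1 list each in FGF2/Activin, PD032, Aurka inh and the combination against 2iLif, 0 in the combination against PD032 (4 at an unadjusted p under 0.05), 1 in the combination against Aurka inh and 2 in PD032 against Aurka inh, in place of 8, 12, 7, 8, 8, 8 and 9. In the same order fry, which tests no list against other genes, called 17, 19, 16, 18, 18, 15 and 17. So 53 of 60 list calls rest on the preset correlation, and 14 of 360 list values with a library left out missed the threshold. The median log2 fold change of all genes lay between -0.034 and 0.081 under the 3 scalings, and which direction had more genes changed with RLE or library size scaling in 4 of 7 comparisons. In the self-test a 1.5-fold change was recovered in as few as 56.7% of cases, so smaller differences at this depth can be missed.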

Other observations

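Some genes had patterns over the groups that no single comparison shows. Cyp1a1, an oxidase induced by foreign compounds, had 40.5 ± 16.2 CPM in PD032 and 56.1 ± 33.6 in the combination, against 0.924 ± 0.0848 in 2iLif, 0.753 ± 0.214 in FGF2/Activin and 2.52 ± 2.04 in Aurka inh. It was thus low in 2iLif, whose medium per the labels carries PD0325901. That medium also carries CHIR99021 and Lif, and contrasts of 2iLif with the inhibitor groups cross the naming styles. Ntn1 had 421 ± 2.55 CPM in 2iLif, 220 ± 31.8 in Aurka inh and 303 ± 14.3 in the combination, against 4.33 ± 0.171 in PD032 and 1.53 ± 0.246 in FGF2/Activin. Pglyrp1 and Nkx1-2 also stood high in the first 3 groups and low in the last 2, as did the Wnt target Axin2, described below. Nkx1-2 stood at 26.1 ± 1.07 in 2iLif, 36.7 ± 3.53 in Aurka inh and 43.1 ± 7.83 in the combination, against 0.16 ± 0.0475 in PD032 and 1.16 ± 0.175 in FGF2/Activin.

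Aurka inh carried Wnt8a, a ligand of early axial patterning, at a higher level than the other groups. It had 28 ± 0.366 CPM there, 5.78 ± 1.06 in the combination and at most 1.57 ± 0.151 elsewhere. Hesx1, a homeobox gene, had 25.4 ± 2.44 CPM in PD032, against 4.15 ± 0.287 in 2iLif, 0.453 ± 0.301 in FGF2/Activin, 0.564 ± 0.196 in Aurka inh and 1.58 ± 0.106 in the combination. Foxd4 had 34.8 ± 6.71 CPM in PD032 and at most 0.192 ± 0.105 elsewhere. These genes were picked by the rule of the comparisons, and their pattern over the 5 groups was noticed after the values were seen.

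Except for the counts over splits of the libraries and the thinning to equal depth, the tests below were chosen only after the result was seen.

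Each comparison's 6 libraries have 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of 10, called 10025 genes in FGF2/Activin against 2iLif, 6660 in the combination against PD032, 5311 in the combination against Aurka inh, 6928 in PD032 against Aurka inh, 9590 in PD032 against 2iLif, 8888 in Aurka inh against 2iLif and 7243 in the combination against 2iLif. The highest of the other splits called 1 gene in PD032 against Aurka inh and 0 in the other 6 comparisons. Each of these splits mixes libraries of both conditions, so any true difference between the conditions adds to the spread and lowers the calls. Their low counts are therefore no evidence against a random grouping.

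Axin2 had 124 ± 6.01 CPM in 2iLif, 97.2 ± 4.69 in Aurka inh and 80.1 ± 2.24 in the combination, against 4.11 ± 0.626 in PD032 and 12.8 ± 1.34 in FGF2/Activin. Sp5 had 65.4 ± 3.17, 13.3 ± 0.73 and 4.22 ± 0.729 CPM in the same 3 groups, 0 counts in PD032 and 1 in FGF2/Activin. RNA of 2iLif, or left-over cells that kept the 2iLif profile, would bring all the abundant transcripts of that medium. The share they would need was taken from 5 of 12 Wnt targets, those lower in PD032 than in Aurka inh and over 2-fold higher in 2iLif than in PD032. Its median was 25.8% in Aurka inh and 16.3% in the combination, but the genes asked for different shares, from 4.38% for Cdx1 to 77.6% for Axin2 in Aurka inh and from 3% to 63.3% in the combination. Of 8607 abundant 2iLif genes, 156 in Aurka inh and 36 in the combination lay under the median share in all 3 libraries. At that share the counts argue against such material as the cause in both groups. At the share of Axin2, 1367 and 393 genes lay under it, but at that of Cdx1 only 18 and 2. With under 5 genes, the test does not decide for Cdx1 in the combination. These shares all cross the naming styles. In Aurka inh and the combination Socs3 kept at most 2.34% and 0.278% of the lowest 2iLif library, and Bcl3 0.75% and 1.26%. The count and its limit of 5 genes were adopted after the values were seen and after 2 earlier forms on 18 marker genes. In these, upper quartiles of 39.3% and 76.8% excluded a mixture in neither group, and lower quartiles of 6.83% and 27.2% excluded it in Aurka inh only. In the combination the markers kept a median of 53.4%, with 3 of 18 under the needed share. Socs3 and Bcl3 are LIF targets, and the profile of 2iLif cells after a change of medium was not measured, so left-over cells that had lost such transcripts stay open in both groups.

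GSK3 inhibition or Wnt activity present in the Aurka inh cultures but not in PD032 alone may explain the Wnt pattern. The median log2 difference of the list between Aurka inh and 2iLif was -0.494, with quartiles of -1.923 and 0.394, too wide to decide. Since the labels name no Aurora compound and no group isolates GSK3, an action of the compound on GSK3 and an effect of Aurora kinase A itself stay untested.

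The second libraries of PD032, Aurka inh and the combination deviated from their groups together. Egr1, an immediate early gene, had 0.644 CPM in the second PD032 library and 14.6 and 26.2 in the others, and 0.783 against 45.9 and 41 in the combination. In Aurka inh it had 24 CPM against 79 and 61.7, a weaker deviation of log2 -1.54, compared with -4.745 and -5.619. The second library also had the highest share of ribosomal protein counts in each of these groups, 5.002% in PD032, 5.848% in Aurka inh and 5.498% in the combination, against at most 4.406%, 5.387% and 4.98% in the others. It lay nearest 2iLif in position as well, at 0.603, 0.493 and 0.268. Lower depth is argued against, since after thinning to 16010904 counts the lowest correlation of these deviations was 0.455. Immediate early genes made up 3 of 43 genes with a shared 2-fold deviation, 6.98%. These 3, Egr1, Fosb and Fos, had the largest mean deviations, and the rest of the 43 were outside the list. The list held only 14 immediate early genes and could not have made up most of the 43, so this share decides nothing. Replicates 1 and 3 had 7 and 2 genes with a shared 2-fold deviation, 3 and 2 of them immediate early. Neither shared handling nor a biological explanation was tested.

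The 76 genes that separate the 9 inhibitor libraries from the other 6 by at least 1 log2 unit include 19 higher and 57 lower in the inhibitor groups. For the pseudogenes among them, 48.7% of the set and 32 of 37 of them lower, a batch in library preparation, sequencing or alignment that follows the file naming is a candidate explanation, since no other split of the groups passed 1.38%. For the 34 protein-coding genes, among them Spry4, Dppa3, Gbx2 and Nkx6-2, batch and medium cannot be told apart because no group crosses the styles. Another split separated 137 protein-coding genes, so their number decides nothing.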
